A study of Homo sapiens with 8 samples.

How the data were processed

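The series holds 8 sequencing libraries from 4 cultures of human HEK293T cells, as labelled. HEK293T is an embryonic kidney line, and the cells were a single clone that carries Cas9, the nuclease that guide RNAs direct to a target. A culture was infected with a lentiviral guide RNA: 3 cultures carried different guides against METTL16 (sgMETTL16-1, sgMETTL16-2 and sgMETTL16-3) and 1 carried the control guide (sgNS). Per the labels' protocols, cells were kept in blasticidin at 10 µg/ml and puromycin at 2 µg/ml for 1 week or longer and were given cycloheximide, which stalls ribosomes, at 100 µg/ml for 5 min. Every culture gave an input RNA library and a library of the RNA fragments that ribosomes protect (footprints, 17 to 34 nt), sequenced as 51-base single-end reads after removal of ribosomal RNA.

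The authors aligned reads with STAR (version not given in the sources used here) and quantified genes with RSEM 1.2.31 against GRCh38, per the submitters' processing notes. The deposited values are TPM (a length-scaled share of transcripts) for 26830 gene symbols in the 8 libraries, and as TPM sums to a fixed total in every library, it shows shares of a library and not absolute amounts. Neither counts nor read totals were used here, so the depth of each library is unknown and counting intervals were not computed. TPM also divides by transcript length, which gives small RNAs large values. Protein-coding genes held from 20.1% to 26.3% of input TPM and from 11.9% to 28.2% of footprint TPM.

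Footprint libraries were sparse. Of the 26830 genes, 22244 were listed at 0 in the sgNS footprints, 21031 in sgMETTL16-1, 20095 in sgMETTL16-2 and 22468 in sgMETTL16-3, and 1870 genes were above 0 in all 4. Among genes above 0 in a pair of footprint libraries, 1 ratio recurred, as it would where both genes hold the same small number of reads. Within a tolerance of 0.02 in the natural log, that ratio was 1.89 for sgNS to sgMETTL16-1, 2.73 for sgNS to sgMETTL16-2 and 2.01 for sgNS to sgMETTL16-3, shared by 28.9%, 23.6% and 33.8% of the genes. A read in the sgNS footprints therefore added more TPM than a read in the other footprint libraries, if these are genes with equal numbers of reads. Of 5630 protein-coding genes under 0.1 TPM in every input, 114 had footprints in at least 2 libraries, so part of the footprint TPM has no counterpart in the input, and its origin is open.

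Gene types and places came from the RefSeq annotation of GRCh38.p14. Of the symbols, 23987 matched by name and 1395 by an older name, and 1448 did not match.

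The 3 comparisons of sgMETTL16 (n = 3 cultures) with sgNS (n = 1) were fitted with limma 3.58.1 in R 4.3.3 on log2(TPM + 1): the input libraries, the footprint libraries, and translation efficiency. Translation efficiency is the footprint to input ratio, tested as the interaction of guide and kind of library over all 8 libraries. Genes with a mean TPM of 1 or more entered a fit, every library was centred on its median gene, and p-values were moderated with an intensity trend and adjusted by Benjamini-Hochberg, with a threshold of 0.05. A log2 change on this scale understates the change of low genes. The lone sgNS culture was assumed to vary like the sgMETTL16 cultures, and as those carry different guides, the p-values measure the spread between guides as well as between cultures. In the input fit the moderated variance came from the intensity trend alone (prior degrees of freedom Inf), so a gene with an unusually wide spread was judged by the typical spread at its level. In the footprints 4586 of all genes were above 0 in sgNS and 4362 in sgMETTL16-3, while 9297 genes were tested. The median tested gene of both libraries was therefore at 0, and centring is poorly defined there. It set every library to the mean of the library medians, which raised values of 0 in both.

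A single value per culture, the median log2 ratio of footprint to input TPM over tested genes, described a global shift in translation efficiency. It used TPM as deposited and an exact two-sided permutation test, for which 1 culture against 3 allows no p below 0.25.

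For gene groups, 33 lists were written down, and lists with 5 or more tested members were tested with limma's camera at a preset correlation of 0.01. Alternatives were an estimated correlation and limma's fry. The groups, tests, gene lists, main alternatives and the rule for named genes were chosen before the data were examined. A few genes that the rule would name are not reported here one by one, though the lists and counts include them. The rule took METTL16 and MAT2A in every comparison, the 6 highest and 6 lowest protein-coding genes past the threshold with a mean TPM of 10 or more and the same direction in all 3 sgMETTL16 cultures (filled by smallest p where fewer passed), and up to 4 members of each described list by smallest p. In the footprint and translation efficiency comparisons, list members were named only for lists past a set test. That departure from the rule, the levels given for marker genes and a few further genes named as such were chosen after values were seen, as were 8 further cell-type lists and the alternatives based on protein-coding genes, on a mean footprint TPM of 50 or more, and on a mean input TPM of 100 or more. For the footprint minimum of 50, several minimums had been looked at first.

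The titles name the guide of both libraries of a culture, and the series design states that samples were profiled and both their input and footprint RNA sequenced, so the culture can serve as a block. Deviations of the input and footprint libraries of a culture correlated at 0.051, 0.013 and 0.063 across 8002 genes. The fit without the block was the main one.

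The fits were tested on simulated data with 200 genes changed. Simulated inputs had the same log2 SD (0.30) at every gene, and simulated footprints had counting (Poisson) noise alone. The rates below hold for those settings and need not carry over to the real libraries. In the simulated input comparison, 20.0% of genes changed 2-fold and 99.5% of those changed 4-fold were recovered, with 3 and 12 unchanged genes called. In the simulated footprint comparison, none of the genes changed 4-fold and 7.14% of those changed 16-fold were recovered (10 genes), with 27 unchanged genes called at 16-fold. The simulated translation efficiency fit called 42 of 168 genes changed 4-fold, 35 of them in the right direction, but also 1300 of the unchanged genes, and with the block it called 0 genes of either kind. The filter at a mean footprint TPM of 50 called 99 unchanged genes at 4-fold without the block and 82 with it. In these simulations, calls for single genes in translation efficiency were therefore weakly controlled. The same fit called no gene of 8002 in the real libraries, so the simulated rates did not carry over. The absence of calls says little.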

Results

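METTL16 is an RNA methyltransferase that modifies U6 small nuclear RNA and the MAT2A mRNA. The series asked how METTL16 affects translation across the genome. It compared 3 cultures with guides against METTL16 with 1 control culture, by input RNA and ribosome footprints (4 libraries of each kind). No read totals accompany the TPM values, so depth is unknown. Input libraries correlated with each other at 0.93 to 0.98 (Pearson r, across 10967 genes, which are not independent replicates). Footprint libraries correlated at 0.23 to 0.59 across 758 protein-coding genes with a mean footprint TPM of 50 or more.

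METTL16 (chromosome 17, 2415715 to 2511888, GRCh38) was at 5.31 TPM in the sgNS input and at 4.72, 5.25 and 4.16 TPM in the inputs of sgMETTL16-1, sgMETTL16-2 and sgMETTL16-3 (4.71 ± 0.545, SD, n = 3). The log2 change was -0.68 (SE 0.36, limma adjusted p = 0.482), or -0.15 on TPM as deposited, so loss of the mRNA was not shown. A guide can disrupt the protein without lowering its mRNA, and protein was not measured here. METTL16 footprints were at 19.76 TPM in sgNS and were listed at 0 in all 3 sgMETTL16 libraries, where from 20095 to 22468 of the 26830 genes were listed at 0. Without counts the number of reads behind 19.76 TPM is unknown, so the footprints do not show a loss of METTL16 either. MAT2A (chromosome 2, 85539168 to 85545281) encodes the enzyme that makes S-adenosylmethionine. Its input level was 16.87 TPM in sgNS and 19.9 ± 8.06 TPM in sgMETTL16, a log2 change of -0.38 after centring (SE 0.38, limma adjusted p = 0.851) that became 0.15 on TPM as deposited.

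Liver transcripts were abundant in every library, although the labels name an embryonic kidney line. All 12 listed hepatocyte markers were at 10 TPM or more in all 4 inputs. Albumin (ALB) ranged from 354 to 1668 TPM in the inputs and from 1604 to 9572 TPM in the footprints, and alpha-fetoprotein (AFP) ranged from 230.1 to 843 TPM and from 1153 to 5208 TPM. The hepatocyte transcription factor HNF4A was at 77.7 to 102 TPM in the inputs. Of 14 listed markers of HEK293 cells, 9 were under 1 TPM in all inputs, among them the neurofilament genes NEFL and NEFM at 0, while KRT8, KRT18, NES, ENO2 and CDH2 were at 6.13 TPM or more in all inputs. Hepatocyte markers did not move with the guide as a group in the input (median log2 change 0.02, limma camera adjusted p = 0.622). Vimentin (VIM) was listed at 0 in all 4 inputs but stood at 188, 85.2, 78.7 and 43.3 TPM in the footprints of sgNS, sgMETTL16-1, sgMETTL16-2 and sgMETTL16-3. Of the blood, epithelial and fibroblast markers 13 of 16, 6 of 11 and 7 of 10 were under 1 TPM in all inputs. Among the others were lysozyme (LYZ), at 194 to 620 TPM in the inputs and 628 to 3442 TPM in the footprints, and the keratin KRT19, at 157 to 498 TPM in the inputs, and 3 epithelial markers were at 10 TPM or more in all inputs.

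**Figure D1:**
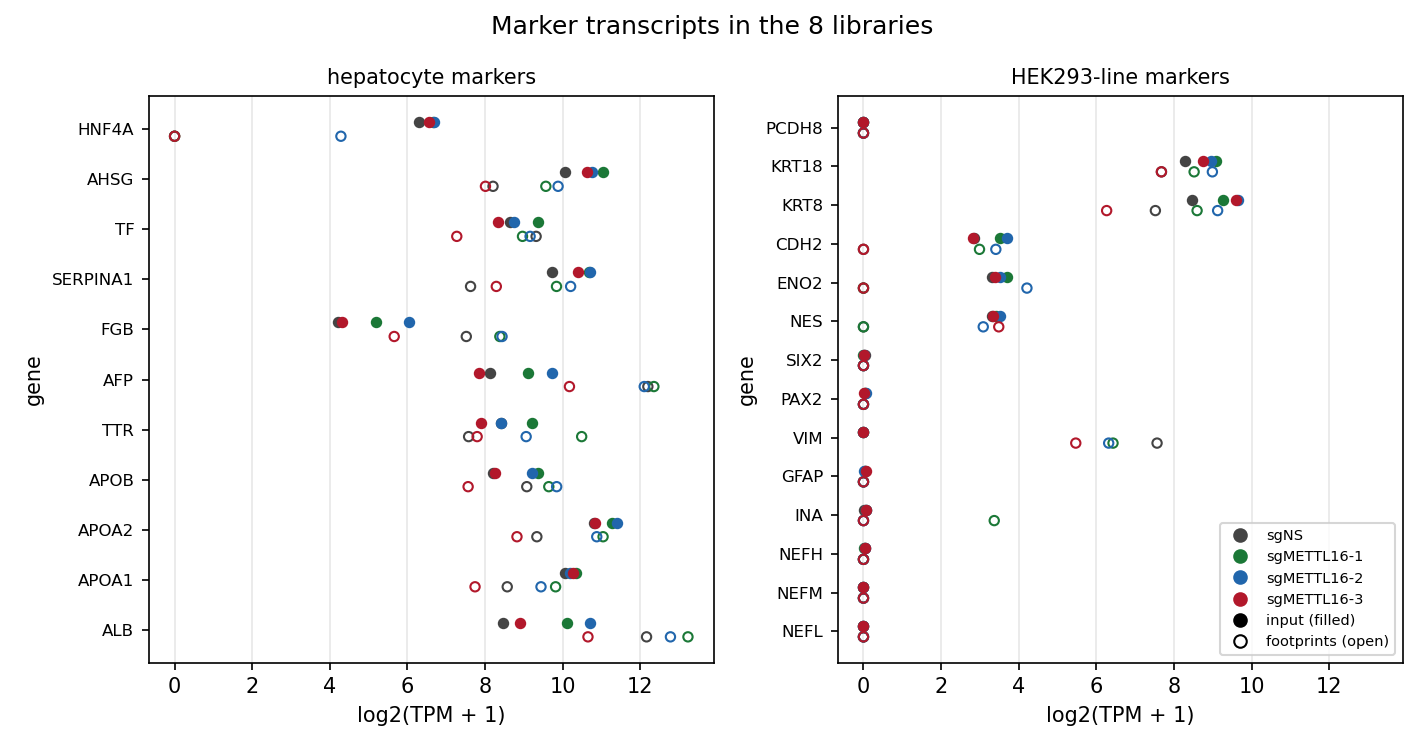
TPM of 11 of the 12 hepatocyte markers and 14 HEK293-line markers on a log2(TPM + 1) axis, with 1 point per library: filled points are input and open points footprints, coloured by culture. The hepatocyte markers lie at 10 TPM or more in the inputs, while VIM lies at 0 in the inputs and at 43.3 to 188 TPM in the footprints.

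The input comparison asked which transcripts differed in abundance between sgMETTL16 and sgNS cells. Replication-dependent histone mRNAs, which cells make in S phase, were the group that stood furthest below the control. Of 45 tested histone genes, 41 passed the threshold, all lower (45 adjusted over the list alone). All 45 were below the lone sgNS library in each of the 3 sgMETTL16 cultures, but as the cultures share that control, 6318 of all 10967 genes also moved the same way in all 3. Their median log2 change was -1.95, between -2.33 and -1.57 in the single cultures (limma camera adjusted p = 5.64e-79, adjusted p = 0.572 with an estimated correlation). HIST1H4B stood at 1477 TPM in sgNS and 321.7 ± 104 in sgMETTL16 (log2 change -2.77, SE 0.45, limma adjusted p = 2.45e-07). HIST1H4D (-2.56), HIST1H4C (-2.56), HIST2H4A and HIST2H4B (-2.47 each) and HIST1H4J (-2.43) followed as the other most lowered protein-coding genes, and HIST1H2AH (-2.42) and HIST1H3F (-1.81) fell as well. HIST2H4A and HIST2H4B carried identical values, and near-identical histone genes share reads, so single copies are uncertain. The list's median remained negative under every scaling, from -2.15 to -1.42. No histone gene passed the threshold on TPM as deposited or rescaled without small structural RNAs, and without sgMETTL16-1 12 of 45 did.

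Genes of DNA replication and division were lower as groups. S-phase genes had a median log2 change of -0.57 over 37 genes, none past the threshold by itself, with MCM7 at -1.13 and UHRF1 at -1.05. Mitotic genes had a median of -0.40 over 36 genes, with 1 past the threshold (5 adjusted over the list alone): AURKB, a kinase of chromosome segregation, fell by 1.37. UBE2C was at -1.18 and BIRC5 at -1.19. The limma camera adjusted p was 3.33e-06 for the S-phase list and 1.17e-05 for the mitotic list, against adjusted p = 0.631 for each with an estimated correlation. On TPM as deposited the median gene moved to 0.46, the S-phase median to -0.04 and the mitotic median to 0.12, so only the S-phase median stayed below 0. Leaving out the centring adds the same amount to every gene's change, so it cannot alter the distance of a list to the median gene. Without sgMETTL16-1 AURKB was at -1.54 and did not pass.

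Targets of p53, the damage-responsive transcription factor, included genes that rose. CDKN1A, an inhibitor of the cell cycle, went from 59.75 TPM in sgNS to 263 ± 92.7 in sgMETTL16 (log2 change 1.52, SE 0.43, limma adjusted p = 0.0162). MDM2, which degrades p53, rose by 1.34, and GDF15, a stress-induced cytokine, by 1.45. These 3 of the 24 tested targets passed over all genes, and 5 of the 24 were higher and 1 lower adjusted over the list alone. PLK3 was at 1.15. The list's median was 0.20 (limma camera adjusted p = 0.00115, adjusted p = 0.631 with an estimated correlation). Without sgMETTL16-1, CDKN1A was at 1.91, MDM2 at 1.49 and GDF15 at 1.69, and none passed the threshold, nor did MDM2 (1.13) and GDF15 (1.49) without sgMETTL16-2. None of the 3 passed with a pseudocount of 0.1, on TPM as deposited, or on TPM rescaled without small structural RNAs or over protein-coding genes. GDF15 did not pass with a pseudocount of 0.5 either. RRM2B, a target named after its values were seen, was at 0.98 and did not pass, but did in 6 other settings, among them a pseudocount of 0.1 (1.66) and protein-coding genes.

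The highest protein-coding genes in sgMETTL16 were led by IGFBP1, a liver-secreted binding protein of insulin-like growth factors. It was at 42.21 TPM in sgNS and 339 ± 52.1 TPM in sgMETTL16 (log2 change 2.43, SE 0.43, limma adjusted p = 3.29e-06). CDA, a cytidine deaminase, rose by 2.34, CYP24A1, which inactivates vitamin D, by 2.31, and the protease inhibitor SERPINE2 by 2.15. The phosphatase gene DUSP5 rose by 2.10 and the scaffold gene AKAP12 by 2.07. Immediate-early genes, which respond to growth signals, had a median of 0.46 over 19 genes: CYR61 (1.55) and DUSP1 (1.57) passed the threshold (4 genes adjusted over the list alone), and KLF6 was at 1.14. The limma camera adjusted p was 1.17e-05 for this list, against adjusted p = 0.631 with an estimated correlation. Of the stress-response list around ATF4, 1 of 28 genes passed: PPP1R15A, a phosphatase subunit that acts on eIF2, rose by 1.34 (list adjusted p = 0.0757, limma camera). The 5 tested epithelial markers had a median of 0.68 with none past the threshold (1 adjusted over the list alone), ELF3 being at 1.11 and KRT19 at 0.97. Cytosolic chaperones had a median of 0.30 over 27 genes with none past it, and of -0.02 in sgMETTL16-3, and HSPH1 was at 0.82. The limma camera adjusted p was 0.00315 and 0.0344 for these 2 lists, against adjusted p = 0.631 for each with an estimated correlation. The chaperone list did not pass on TPM as deposited, without sgMETTL16-1, without sgMETTL16-2 or over protein-coding genes (limma camera adjusted p = 0.338, 0.0528, 0.4 and 0.139), nor the epithelial list over protein-coding genes (adjusted p = 0.0783). Without sgMETTL16-1, CYR61 (1.85), DUSP1 (1.88) and PPP1R15A (1.53) did not pass.

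Genes for ribosomal proteins and the respiratory chain were lower relative to the median gene. Cytoplasmic ribosomal protein genes had a median log2 change of -0.50 over 77 genes, with RPS27 alone past the threshold (-1.48), also adjusted over the list alone, and RPS21 at -1.42. Nuclear genes of oxidative phosphorylation had a median of -0.43 over 62 genes, and NDUFB8 (-1.47) and NDUFS6 (-1.42), subunits of complex I, passed (2 adjusted over the list alone). Spliceosome genes, including partners of U6, had a median of -0.34 over 39 genes with SNRPF past the threshold (-1.41), also adjusted over the list alone. Cholesterol synthesis genes had a median of -0.39 over 24 genes, with 1 past it (2 adjusted over the list alone) and FDPS at -1.23. Host genes of small nucleolar RNAs (median -0.61, 13 genes), SR and hnRNP genes (-0.34, 32 genes) and targets of Wnt, Notch and Hedgehog (-0.55, 11 genes) had no member past the threshold, over all genes or adjusted over the list alone. The limma camera adjusted p of these 7 lists lay between 1.35e-05 and 0.0401, and with an estimated correlation between adjusted p = 0.572 and adjusted p = 0.668. On TPM as deposited the medians of ribosomal protein, respiratory, spliceosome, cholesterol, and SR and hnRNP genes turned positive (0.03, 0.09, 0.18, 0.13 and 0.19), with the median gene at 0.46. Their distance to the median gene is the same with and without centring, so this setting does not test it. The Wnt, Notch and Hedgehog list did not pass on TPM as deposited or without sgMETTL16-1 (limma camera adjusted p = 0.061 and 0.12), nor SR and hnRNP genes (adjusted p = 0.0914) and cholesterol genes (adjusted p = 0.0688) without sgMETTL16-3. Without sgMETTL16-1, RPS27 (-1.51), NDUFB8 (-1.57), NDUFS6 (-1.47) and SNRPF (-1.37) did not pass. With no filter, spliceosome genes (-0.20) and SR and hnRNP genes (-0.19) did not lie below the median gene (-0.21), while the other lists of this paragraph did. With quantile normalization the median of ribosomal protein genes was -0.17.

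Several small structural RNAs rose. SNORD118, the U8 RNA that acts in ribosomal RNA processing, went from 4.14 TPM in sgNS to 149 ± 25.6 in sgMETTL16 (log2 change 4.32, SE 0.40, limma adjusted p = 3.57e-23). The spliceosomal RNAs RNU5B-1 (3.86) and RNU11 (3.11) and the vault RNA VTRNA1-1 (2.94) rose too. Of 22 tested members of the list 6 rose (9 higher and 1 lower adjusted over the list alone) and 8 lay below 0, with a median of 0.79 and a limma camera adjusted p of 5.9e-12 (adjusted p = 0.631 with an estimated correlation). All small nuclear RNAs together held 18.9% of input TPM in sgNS and from 14% to 15.6% in the 3 sgMETTL16 cultures.

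No member of the m6A machinery (23 genes), of the methionine and S-adenosylmethionine cycle (23) or of eIF3 (13) passed the threshold in the input, over all genes or adjusted over the list alone. Their medians were -0.17, -0.09 and 0.17 (limma camera adjusted p = 0.514, 0.963 and 0.379). In these lists HNRNPA2B1 was at -0.97, TRMT112 at -0.86, AMD1 at 0.72, SHMT2 at -0.72 and EIF3M at 0.75, while ZC3H13 (-0.48) and MTR (-0.40) turned positive on TPM as deposited. For the methionine list, the HEK293 markers, other initiation factors and ribosome biogenesis the test pointed up while the median lay below 0 (adjusted p from 0.616 to 0.963). The other lists without a call, with adjusted p from 0.123 to 0.622, were the hepatocyte markers, tRNA synthetases, elongation factors, mitochondrial ribosomal proteins, proteasome, glycolysis and hypoxia, interferon response and nuclear long non-coding RNAs. Of these, mitochondrial ribosomal proteins passed on TPM as deposited, without sgMETTL16-2 and over protein-coding genes (limma camera adjusted p = 0.00941, 0.014 and 0.033), and tRNA synthetases without sgMETTL16-3 (adjusted p = 0.0194). Adjusted over the list alone, 2 glycolysis and hypoxia genes and 1 nuclear long non-coding RNA were lower. Blood and fibroblast markers had 3 tested genes each and mitochondrially encoded genes none, too few for the test.

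In total 310 of 10967 genes passed in the input, 173 higher and 137 lower. Of these, 83 higher and 89 lower genes were protein-coding (9917 tested), and 62 higher and 22 lower were small nucleolar RNAs (236 tested). Of the 15 lists past the threshold (of 30), none held with an estimated correlation or by fry. On TPM as deposited 23 genes passed, 22 higher and 1 lower, among which IGFBP1 and the 4 small RNAs named above were the only named genes. Without sgMETTL16-1 or sgMETTL16-3 the count was 95 or 670.

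**Figure D2:**
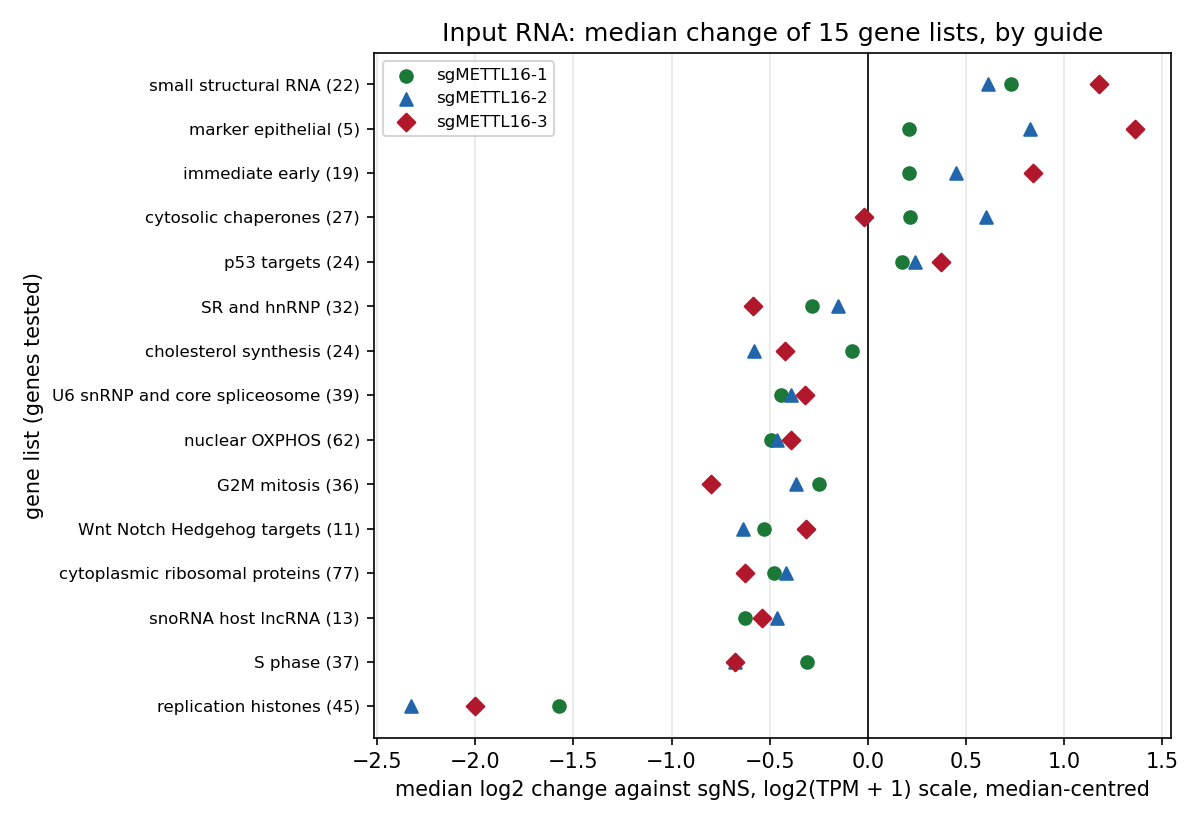
Median log2 change of the 15 gene lists past the threshold in the input comparison, relative to sgNS, with 1 point per sgMETTL16 culture and no error bars; the number of genes tested follows each list's name. Replication histones lie lowest (-1.57 to -2.33), and values are after median-centring, without which the median gene lies at 0.46 and 6 of the lower lists (mitotic, ribosomal protein, respiratory, spliceosome, cholesterol, SR and hnRNP) lie above 0.

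The footprint comparison asked which mRNAs had more or fewer ribosome-protected fragments. No gene of 9297 passed with limma (1189 had an unadjusted p under 0.05), and no list of 29 passed with camera, with an estimated correlation, or by fry. The genes with the smallest p were mostly at 0 on 1 side. NDUFA1, a complex I subunit, FABP1, a fatty-acid binding protein of liver, S100A11, APOM, FAU and COX6C were listed at 0 in the sgNS footprints, and FABP1 stood at 338, 234 and 320.5 TPM in sgMETTL16-1, sgMETTL16-2 and sgMETTL16-3. HIST1H2AI (390 TPM), the metallothionein MT1G (214.6 TPM) and ABHD12 (134 TPM) were seen in sgNS and listed at 0 in all 3 sgMETTL16 libraries. MAT2A footprints were at 74.14 TPM in sgNS and at 10.71, 20.89 and 28.44 TPM in sgMETTL16 (log2 change -4.07, SE 2.34, limma adjusted p = 0.423), and the change was -1.94 on TPM as deposited. On TPM as deposited 580 genes were called, and all 580 were listed at 0 in all 3 sgMETTL16 libraries (531) or in sgNS (49). Without sgMETTL16-3 the count was 560, of which 522 were listed at 0 in all 3 libraries of that fit, so that their fitted change came from centring alone.

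Translation efficiency, the question in the series' title, was compared as the footprint to input ratio. Part of the footprint TPM had no counterpart in the input, so a ratio need not describe translation of the input RNA alone. No gene of 8002 passed with limma (731 had an unadjusted p under 0.05), with or without the culture as a block. The complex I subunit NDUFA1, the ribosomal protein fusion gene FAU, HIST1H2AJ, the cytochrome oxidase subunit COX6C, SSR2 and PARK7 had the smallest p among higher genes (limma adjusted p = 0.539 for each). All 6 were listed at 0 in the sgNS footprints, so no fold is given. FAU footprints stood at 220.2, 533.7 and 52.2 TPM in sgMETTL16-1, sgMETTL16-2 and sgMETTL16-3, with an input of 426 TPM in sgNS. Among lower genes ABHD12, HIST1H2AI and SEC22C came first (limma adjusted p = 0.539 for each), listed at 0 in all 3 sgMETTL16 footprint libraries. Of 29 lists, replication histones were higher (median 2.19 over 30 genes, limma camera adjusted p = 0.035) and small structural RNAs lower (median -1.02 over 19 genes, adjusted p = 0.0351). Both lists stood at adjusted p = 0.998 with an estimated correlation. The histone footprints alone had a median of -2.94 after centring (limma camera adjusted p = 0.905) and of -0.82 on TPM as deposited. Each comparison was centred on its own tested genes, so the medians of a list in different comparisons cannot be subtracted from each other. Neither list had a member past the threshold over all genes, while 1 histone gene was higher and 3 small RNAs lower adjusted over the list alone. Both medians include genes listed at 0 on a side, for which no bound is available without counts. Neither passed on TPM as deposited, where the medians were 0.90 and -2.31, or without sgMETTL16-1 or sgMETTL16-2. Without sgMETTL16-3 the histones passed (median 1.76) and the small RNAs did not (-1.22), and with protein-coding genes alone the histone median lay at -1.43 although the test still pointed up. Of the histone genes with the smallest p, HIST1H4K was at 176.6 TPM in the sgNS footprints and at 743, 771 and 88.5 TPM in sgMETTL16 (log2 change 4.14, SE 1.13, and 0.52 over protein-coding genes alone), while HIST1H2AJ, HIST1H2AB and HIST1H2BM were listed at 0 in sgNS. Of the small RNAs, VTRNA1-1, RNU4-2 and RNU6ATAC were listed at 0 in all 3 sgMETTL16 footprint libraries, and RNY3, which pointed up, was listed at 0 in sgNS. METTL16 did not pass (limma adjusted p = 0.789, footprints at 0 in sgMETTL16), nor did MAT2A (log2 change -0.79, SE 2.51, limma adjusted p = 0.896), which was at -2.08 on TPM as deposited.

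The median log2 ratio of footprint to input over 8002 genes was -0.75 in sgNS and -0.53, -0.32 and -1.32 in sgMETTL16-1, sgMETTL16-2 and sgMETTL16-3 (-0.72 ± 0.53, SD, n = 3). The sgMETTL16-3 footprint library stood apart in its composition, with 11.9% of TPM in protein-coding genes and 39.9% in small nucleolar RNAs, against 26.8% to 28.2% and 19.8% to 29.3% in the others. The difference of 0.03 was smaller than the spread between the sgMETTL16 cultures (exact permutation p = 1). The medians of the 2 sparsest footprint libraries depended on the pseudocount. With 0.1 they were -1.30 in sgNS and -3.25 in sgMETTL16-3, against -0.56 in sgMETTL16-1 and -0.35 in sgMETTL16-2. They rest in part on genes at or near 0, so the small difference does not show that translation efficiency was unchanged. Over 758 protein-coding genes with a mean footprint TPM of 50 or more, the ratio was 1.64 in sgNS and 1.01, 0.86 and 0.32 in sgMETTL16 (difference -0.91, exact permutation p = 0.25, the smallest the design allows). With both kinds of library rescaled over protein-coding genes, that difference was -0.32 (exact permutation p = 0.25).

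**Figure D3:**
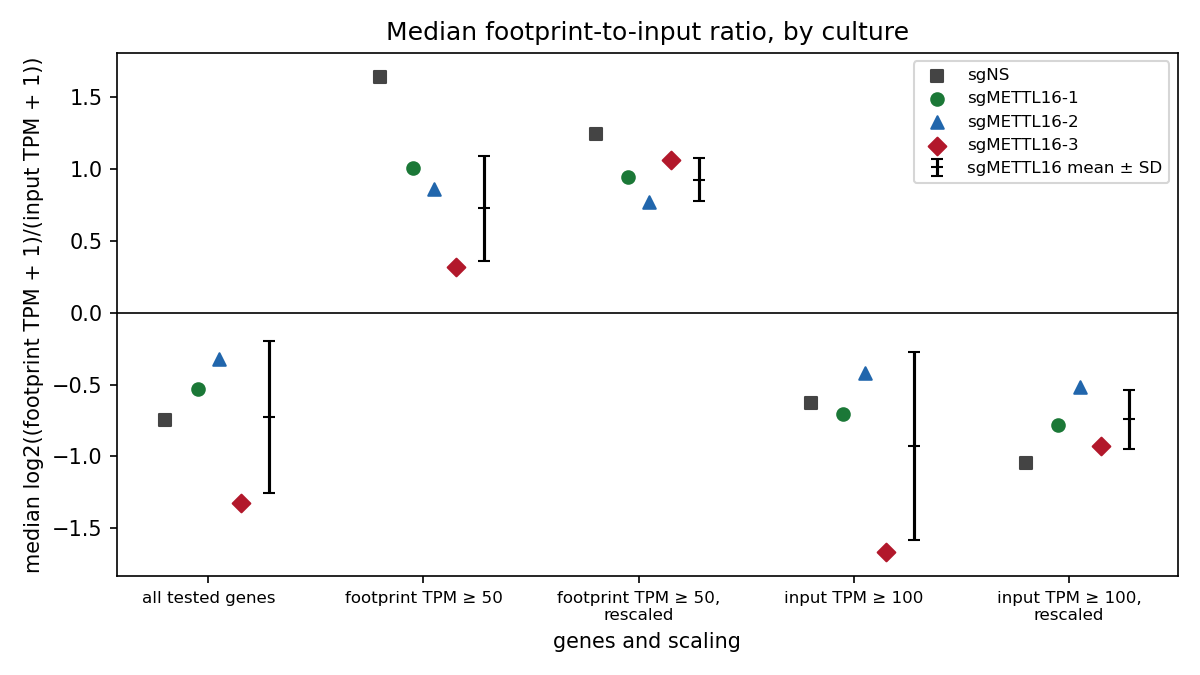
Median log2 ratio of footprint to input TPM in the 4 cultures for 5 sets of genes or scalings, with the sgMETTL16 mean and SD (n = 3) as bars beside the points. The sgNS point lies among the sgMETTL16 points over all tested genes (-0.75) and above them over genes with a mean footprint TPM of 50 or more (1.64), while over genes with a mean input TPM of 100 or more, rescaled, it lies below them (-1.04).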

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

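Alternatives on protein-coding genes, on a mean footprint TPM of 50 or more and on a mean input TPM of 100 or more, and the test with another lone library, were chosen after seeing the data. The input count of 310 was within 1.5 times under both other pseudocounts, both filters, no trend, robust moderation and protein-coding genes alone (220 to 395). It fell to 23 on TPM as deposited (22 higher, 1 lower) and to 65 with TPM rescaled without the small structural RNAs (33 higher, 32 lower), and rose to 532 with quantile normalization (337 higher, 195 lower). Leaving out 1 sgMETTL16 culture gave 95 (without sgMETTL16-1) to 670 genes (without sgMETTL16-3); the cause was not tested. With the control exchanged for a sgMETTL16 culture as the lone library, sgMETTL16-1 gave 29 genes, sgMETTL16-2 gave 8 and sgMETTL16-3 gave 0, so 1 of 4 choices gave as many as the real 310, the highest other being 29; 4 choices allow no share under 0.05. In translation efficiency, sgMETTL16-3 as the lone library gave 337 genes, of which 309 were listed at 0 in the footprints of all other cultures; whether a structure of the libraries or the fit's calls of unchanged genes lies behind this was not tested.

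The count of lists past the threshold in the input (15) fell to 0 with an estimated correlation and to 0 by fry, and was 12 to 15 otherwise, but not of the same lists: 1 or 2 were lost on TPM as deposited and without a culture, and 4 on protein-coding genes, of which 2 had too few such genes to test. In translation efficiency the 2 lists fell to 0 with an estimated correlation, by fry and on TPM as deposited, to 1 with protein-coding genes alone, and to between 0 and 3 without a sgMETTL16 culture. At a mean footprint TPM of 50 the 2 that passed differed: small structural RNAs (median -1.46) did, replication histones did not (1.34, limma camera adjusted p = 0.0535), and oxidative phosphorylation genes did (0.64, adjusted p = 0.0198, 7 genes higher), each list at adjusted p = 0.68 with an estimated correlation. With the block as well, all 3 passed at the preset correlation. In the footprints, leaving out 1 culture gave 0 to 6 lists, the 6 without sgMETTL16-3, in the fit where most calls came from centring.

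The footprint count of 0 rose to 6 with no filter, 37 at a mean TPM of 5, 580 on TPM as deposited, 606 with quantile normalization and 1 at a mean footprint TPM of 50, and to between 0 and 560 without a sgMETTL16 culture, 522 of the 560 being genes at 0 in all 3 libraries fitted. The translation efficiency count of 0 rose to 92 at a mean TPM of 5, 14 on TPM as deposited, 148 with quantile normalization, 11 rescaled without small structural RNAs and 49 at a mean footprint TPM of 50. The calls were mostly genes at 0 in sgNS or in all 3 sgMETTL16 footprint libraries: 580 of 580, 605 of 606 and 37 of 37 in the footprints, and 91 of 92, 14 of 14, 147 of 148 and 47 of 49 in translation efficiency. With the replicate block by culture, translation efficiency gave 0 genes and 2 lists, and 34 genes in place of 49 at a mean footprint TPM of 50.

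The global shift of 0.03 moved to -0.79 at a mean TPM of 5 and to -0.91 over protein-coding genes with a mean footprint TPM of 50 (gene type and minimum both changed), and was between -0.18 and 0.32 without a sgMETTL16 culture; the cause was not tested for the filter at 5.

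None of the genes whose change turned had passed the threshold, and the cause was not tested. On TPM as deposited MAT2A went to 0.15, ZC3H13 to 0.049, MTR to 0.12, LYL1 to 0.51, PDGFRB to 0.51, NES to 0.10, ENO2 to 0.22 and TTR to 0.10 in the input. LYL1 and PDGFRB went to 0.28 and 0.028 with pseudocount 0.1, to 0.093 and 0.0011 with pseudocount 0.5, to 0.12 and 0.12 with no filter, and to 0.56 and 0.35 rescaled without small structural RNAs. Leaving out 1 culture gave from -0.20 to 0.19 and from -0.13 to 0.17, positive without sgMETTL16-2 alone. LYL1 went to 0.10 with quantile normalization and 0.20 on protein-coding genes, and TTR to 0.061 with quantile normalization. MAT2A translation efficiency went to 0.23 with pseudocount 0.1 and lay between -2.37 and 0.35 without a culture, positive without sgMETTL16-1 alone. Of all values of single genes under an alternative, 1166 of the input, 167 of the footprints and 263 of translation efficiency kept direction and side of the threshold, and 104 input values no longer passed. The depth of the footprint libraries limits everything that rests on single genes in them.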

Other observations

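The tests of TPM composition, S phase, T-lymphoid, HEK293T and liver cells and the METTL16 effect were chosen only after the result was seen; those of gene span and of genes chosen by input TPM, the latter added after the data were seen, were set before their own results.

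The genes of this paragraph were chosen after their values in the inputs were seen, and apart from small nucleolar RNAs, of which SNORD118 was on a tested list, they belong to no list that was tested. TIMP1, an inhibitor of matrix metalloproteinases, went from 24.01 TPM in sgNS to 136 ± 40.6 in sgMETTL16 (log2 change 1.88, limma adjusted p = 0.000405), and PLAU rose by 1.65, THBS1 by 1.51 and SPP1 by 1.54, and HMOX1, which degrades heme, by 1.52. Of the metallothioneins, which bind zinc and copper, 3 of the 6 tested MT1 genes passed: MT1G fell by 2.22, MT1F by 1.63 and MT1E by 1.37. MT2A was at -0.52 and did not pass (0.011 on TPM as deposited). Without sgMETTL16-1, TIMP1 (2.20), THBS1 (1.81), SPP1 (1.97), HMOX1 (1.97), MT1G (-2.32), MT1F (-1.83) and MT1E (-1.38) did not pass, nor did SPP1 (1.03) and MT1E (-1.29) without sgMETTL16-2, and on TPM as deposited none of these 8 genes passed. Among small nucleolar RNAs, 42 of 103 tested SNORA genes were higher and 2 lower, while of 133 SNORD genes 20 were higher and 20 lower. On TPM as deposited 8 SNORA genes were higher and 0 lower, and 2 SNORD genes higher and 0 lower. Without sgMETTL16-1 the counts were 18 and 2 for SNORA and 6 and 6 for SNORD, and without sgMETTL16-3 33 SNORD genes were lower.

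Histone mRNAs lay lower in the sgMETTL16 inputs by a median of -1.95. Poorer recovery of short transcripts was examined with 490 other protein-coding genes of the same genomic span (389 to 3296 bp). Their median was -0.32, above the upper quartile of the histones (-1.79) but below the median of all tested genes (-0.06). Genomic span is not mRNA length and the range was wide, so the test cannot exclude a loss of the shortest mRNAs. A changed share of small RNAs is argued against as the whole cause, since with TPM rescaled over protein-coding genes the list stood at -1.73 uncentred (quartiles -1.89 and -1.51), and 38 of 42 genes passed once that scale was centred. A smaller share of cells in S phase may account for it as a hypothesis: the S-phase list was at -0.57, but its call ends with an estimated correlation, and with 1 control culture a guide effect and a difference in growth or density of that culture cannot be told apart.

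Transcripts of cells the labels do not name were present in all libraries. Liver-derived cells are a candidate explanation for the input, as 12 of 12 hepatocyte markers passed 10 TPM in every input, and a mixture of HEK293T cells with liver RNA stays open, since 9 of 14 HEK293-line markers were under 1 TPM in all inputs, VIM at 0 among them, while NES (8.94 to 10.42 TPM), ENO2 (8.93 to 12.06) and CDH2 (6.13 to 12.03) were present. In the footprints, 114 of 5630 protein-coding genes under 0.1 TPM in every input had footprints in at least 2 libraries, among them INS (62.5 to 262.5 TPM), LDHB (16.1 to 88.1) and SASH3 (10.6 to 63.7). T-lymphoid RNA could be a source: 13 of 31 silent T-lymphoid genes had footprints in at least 2 libraries. Most of these 13 had been seen with footprints before the test, so that share is no support by itself. CORO1A, the most abundant of the list in sgNS, ranged from 41.1 to 208 TPM (2.31 to 3.74 in the inputs, where 2 of the 42 listed genes passed 10 TPM). Over the 20 silent genes not already seen, 2 had such footprints, or 10.0% against 2.00% of other genes (Fisher's exact test, two-sided, adjusted p = 0.244 over 8 lists). T-lymphoid RNA as a source therefore stays open, as does carry-over from libraries of other cells, which was not tested. Of the other lists, pancreatic islet genes had 3 of 15 (adjusted p = 0.0246, a list chosen after INS and SST were seen), and B-lymphoid, myeloid, erythroid, neuron, skeletal muscle and fibroblast genes had 0.

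The median footprint to input ratio was lower in sgMETTL16 than in sgNS by 0.91 over protein-coding genes with a mean footprint TPM of 50 or more. After rescaling over protein-coding genes the difference was still -0.32, larger than the SD of 0.149 between the sgMETTL16 cultures (exact permutation p = 0.25, the smallest possible). With 1 control culture this cannot decide whether a changed share of protein-coding genes is the whole cause. Choosing genes on footprint TPM may contribute, if the recurring ratios mean that a read adds most TPM in the control: with genes chosen on input TPM of 100 or more the difference was 0.30 rescaled (SD 0.21, exact permutation p = 0.5) and -0.30 as deposited (SD 0.66, exact permutation p = 0.75), so its sign depends on the scaling. Whether loss of METTL16 lowers translation of most mRNAs cannot be told apart from a property of the 1 control culture. TPM also shows shares of a library, so a fall common to all footprints would not appear in this ratio however many cultures were used.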
